A study of Haloarcula hispanica ATCC 33960 with 16 samples.

How the data were processed

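Chromatin immunoprecipitation followed by sequencing was applied to HA-tagged TrmB and to the untagged parent strain of Haloarcula hispanica. Per the labels, the parent strain lacks pyrF and the tagged strain carries the trmB fusion in that background. Per the labels' protocols, 2 parent and 4 tagged cultures were started from independent colonies, and tagged cells were moved to medium with or without 0.1% glucose. There are 6 tagged libraries, so some cultures gave more than 1 library, and which libraries share a culture is not given in the sources used here. Groups and replicate letters were taken from the sample titles, and the descriptions of 2 libraries name another letter than their titles. Only the permutations of library labels measure the spread between libraries; other p-values rest on positions, regions or peaks as the units, which are not replicates.

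The authors deposited 1 peak list for each immunoprecipitated library, with start, end and a score for each peak, and per the file headers the lists come from the peak caller MOSAiCS. Peaks were thus called per library and not on pooled samples. The submitters' processing notes name Trim Galore 0.4.3, cutadapt 2.3, FastQC 0.11.7, Bowtie2 2.3.4.3, SAMtools 1.9 and 1.10, R 4.1.2 and bedtools 2.30.0. The caller's version and threshold, how inputs entered the calling, and the genome build are not given in the sources used here. The score is the authors' own value for each deposited peak. Within each list the peak widths were multiples of 1 bin width, between 103 and 213 bp, and a peak spanned at least 2 bins. The bin width was 104 and 213 bp in untagged A and B, 104, 200, 103 and 204 bp in tagged A to D without glucose, and 167 and 103 bp in tagged A and B with glucose. For all 1356 peaks the score times the number of bins was a whole number (tolerance 1e-06), so each score can be read as a mean of whole numbers per bin. Depth per library is unknown, which leaves the sensitivity of each list unknown, and scores were used only to rank or describe peaks within their own list.

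Replicons were named from the sequence names in the lists, as background, and the last called base in any list was taken as the length of a replicon. Positions are printed counted from 1. Peaks of all 8 lists that overlapped by at least 1 bp were merged into regions. A region counted as reproducible in a group when more than 50% of its libraries had a peak in it, which is at least 3 of 4 without glucose and 2 of 2 with glucose. Regions with a peak in an untagged library were set aside. The rank of a region in a list is the rank of its highest peak, and the percentile is the rank as a share of the list's length, with the highest peak at 100. A region was named if it was among the first 30 of the reproducible regions without glucose, ordered by the number of tagged libraries and then by mean percentile. Regions with an untagged peak that were reproducible in a tagged group were also named, as were up to 10 regions reproducible in 1 medium and called in no library of the other. This rule was written for the genes at such regions, and with no annotation used here it was applied to the regions themselves. The 12 regions with the highest mean percentile without glucose among the 121 reproducible ones were added after the data were examined.

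Peak numbers and covered lengths were compared by exact permutation of the 15 splits of 4 against 2 libraries, two-sided, with the p taken as 2 times the smaller tail. The grouping of lists by medium was tested by exact permutation of the medium over the 6 tagged libraries, one-sided. Pairwise overlap was tested against 10000 circular shifts of 1 list within each replicon, one-sided, with Benjamini-Hochberg adjustment over 28 pairs. Regions per replicon were tested against 10000 random placements in proportion to replicon length, two-sided, adjusted over the 3 replicons. Scores of shared and other peaks were compared by 100000 permutations within a list, two-sided, adjusted over 6 lists. The merging and overlap steps were tested on simulated lists. Over 20 runs 98.1% of the planted reproducible regions were recovered, with 0.45 regions per run that were not planted. Planted sharing between lists passed in 20 of 20 runs, and lists without sharing passed in 1 of 20. The simulated peaks were capped in width well below the widest real ones. Each planted site was placed in every list of its groups, and the remaining peaks were scattered at random. The runs thus tell nothing about very wide peaks, sites missed by some lists or other background shared between lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

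The groups, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives were a stricter list (the upper 50% by score), other definitions of overlap (at least 50% of the shorter peak, or midpoints within 250 bp), other numbers of libraries required, untagged peaks ignored, peaks within 500 bp joined, a replicate block, and leaving out each library in turn. Leaving out the 2 no-glucose libraries with bins of 200 bp or wider was added after the data were examined. Planned tests of 17 gene lists, of positions relative to genes and start codons, and of a TrmB sequence motif need a genome and were not analysed here.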

Results

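The data are peak lists from chromatin immunoprecipitation sequencing of TrmB in Haloarcula hispanica, an extremely halophilic archaeon. TrmB is a DNA-binding transcription regulator whose relatives in other archaea are known to respond to sugars. The tagged strain carries trmB fused to a haemagglutinin (HA) epitope in a uracil auxotroph lacking pyrF, and that auxotroph, without the fusion, served as the untagged control. All immunoprecipitations used an anti-HA antibody. Cells grew in a casamino acid medium with uracil, and part of the tagged cultures received 0.1% glucose. Of the 16 samples in the labels, 8 are immunoprecipitated libraries with a peak list and 8 are inputs, which were not analysed here. The immunoprecipitated libraries fall into 3 groups, with 2 untagged libraries (A and B), 4 tagged libraries without glucose (A to D) and 2 tagged libraries with glucose (A and B). No untagged library came from medium with glucose. Peaks were called separately in each library, and the lists hold 1356 peaks in all. Read totals are not given in these lists, so the depth behind each peak is unknown. Scores are the authors' own and were used only within a list, to rank its peaks or to describe a peak as a multiple of that list's median. No gene annotation was used, so regions are named by replicon, start and end, counted from 1.

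The first comparison asked which enrichment depended on the tagged protein. Tagged cells grown without glucose gave 195 ± 51.3 peaks (SD, n = 4), against 22 ± 2.83 (SD, n = 2) in untagged cells, a difference of 173 peaks. Peaks covered 136 ± 58.9 kb (SD, n = 4) in tagged cells without glucose and 13.6 ± 10.3 kb (SD, n = 2) in untagged cells. Within each list, the highest score was 13.5, 23.5, 6.40 and 61.4 times the list's median in tagged libraries A, B, C and D without glucose, and 1.22 and 1.09 times in untagged A and B. It was 7.96 and 2.21 times the median in tagged libraries A and B with glucose, and only 2 peaks of that list B exceeded 2 times its median. In both glucose lists the highest peak lay at main chromosome 212568–219270, where both untagged lists also had peaks. The other such peak of glucose B lay at main chromosome 1775544–1782223, which also overlapped untagged peaks. These highest values with glucose thus cannot be credited to the tagged protein. No tagged library overlapped the untagged ones in peak number or covered length. The exact permutation test, two-sided, gave p = 0.133 for both measures, which is the smallest value that 4 against 2 libraries allow.

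**Figure D1:**
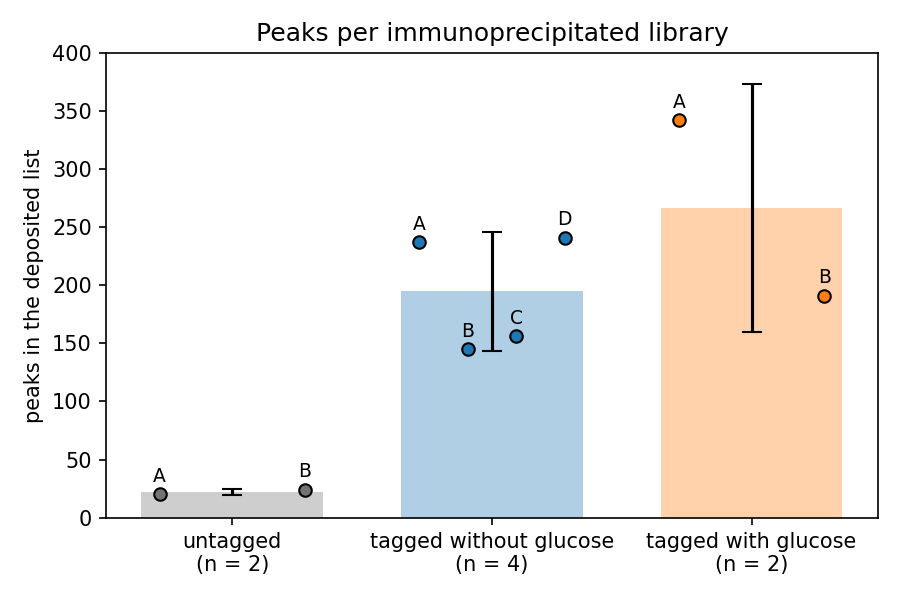
Number of peaks in each deposited list (points, with the replicate letter) for the 3 groups of libraries; bars are group means and error bars are SDs. The untagged lists hold 20 and 24 peaks, the lists of tagged cells without glucose 145 to 241, and those with glucose 191 and 342.

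Peaks from the 8 lists merged into 445 regions. Without glucose, 121 regions had a peak in more than 2 of the 4 tagged libraries and in no untagged library, and 86 of them were called in all 4. The median peak width was 309 to 612 bp in these lists, and the widest peak spanned 7548 bp. The 6 with the highest mean percentile without glucose ranked 11 or better in each of the 4 lists. The region at 1355988–1360883 on the main chromosome ranked 2 in each of the 4 lists, at 6.03 to 29.6 times the list median. The region at 130356–137903 on plasmid pHH400 ranked 3, 3, 4 and 4 in libraries A to D, and main chromosome 2561628–2565095 ranked 4, 7, 3 and 5. The others were main chromosome 1314372–1318247, with ranks of 5, 5, 6 and 7, main chromosome 831504–832799, with 7, 4, 11 and 3, and main chromosome 1209720–1214411, with 6, 6, 5 and 8. Main chromosome 168096–169399 ranked 1 in all 4 lists without glucose. It was set aside from the 121 because untagged library B had a peak within it, of rank 17 among 24 and 0.979 times that list's median. The count of 121 regions was 67 when only the upper 50% of each list by score was kept, the untagged lists included.

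Untagged peaks marked 31 regions. Of these, 8 had no tagged peak, 15 were reproducible in tagged cells without glucose, and 12 were called in all 6 tagged libraries. Peaks in both untagged libraries lay in 5 regions, all on the main chromosome. Main chromosome 212568–219270 had the highest peak of both glucose lists and ranked 15 to 17 in the lists without glucose. Main chromosome 1775544–1782223 ranked 2 in both glucose lists and 20 to 26 without glucose. Main chromosome 2759100–2760509 ranked 4 in both glucose lists and 12 to 16 without glucose. Main chromosome 2993809–2995311 was called in all 6 tagged lists at ranks of 23 to 40, and main chromosome 2715750–2718944 was called low in 5 of them. Second chromosome 8350–14194 had a peak in untagged library B and ranked 3 in both glucose lists. The untagged lists shared peaks with the tagged ones beyond chance. On average 67.6% of the untagged peaks overlapped a peak of a tagged list, against 7.65% after circular shifts (12 pairs of lists, highest Benjamini-Hochberg adjusted permutation p = 0.0002).

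The second comparison asked where TrmB enrichment differed between media. Of the 121 regions reproducible without glucose, 93 were also called in both glucose libraries, 13 in 1 of them and 15 in neither. With only the upper 50% of each list by score, 49 regions were called in both media. With peaks joined only where their midpoints lay within 250 bp, 72 regions were called in both media. Under that rule 120 regions were reproducible without glucose, and 19 of these were in no glucose list. The count of 15 became 26 when no-glucose library C was left out and 28 when glucose library A was left out. Either step loosens the rule, so the count could hardly fall. The 10 of these 15 called in all 4 lists without glucose include some of the strongest regions in those lists. Main chromosome 2561628–2565095 and 831504–832799 had no peak in either glucose list. The same held for main chromosome 2236044–2240123, with ranks of 9, 12, 10 and 10 in libraries A to D without glucose, and for main chromosome 2920464–2921687, with ranks of 14, 10, 15 and 11. It also held for second chromosome 324564–326195, with ranks of 19, 13, 13 and 13, and for main chromosome 959600–960227, with ranks of 17, 11, 29 and 9. Lower in the lists, main chromosome 2143800–2144447, 45492–46103 and 1985736–1986347 and plasmid pHH400 41400–43451 were likewise called in every library without glucose and in none with it. Main chromosome 168096–169399, the leading peak without glucose, was absent from glucose list A and ranked 183 of 191 in glucose list B.

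Other leading regions kept a peak in both glucose lists. Main chromosome 1355988–1360883 ranked 245 of 342 in glucose list A and 11 of 191 in glucose list B. Plasmid pHH400 130356–137903 ranked 101 and 6 in glucose A and B, main chromosome 1314372–1318247 ranked 103 and 24, and main chromosome 1209720–1214411 ranked 165 and 46. These ranks come from lists of different lengths and describe each list alone. The glucose peaks at these regions stood at 0.885 to 1.43 times the list median, against 2.96 to 29.6 times for their highest peaks without glucose. Main chromosome 2634456–2637931 and 2697084–2704223, chosen after their values were seen, ranked 6 to 12 in every list without glucose, 252 and 185 in glucose list A, and had no peak in glucose list B. Their glucose A peaks, at 2637431–2637931 and 2698386–2698719, lay apart from the highest peaks of libraries A and C without glucose, at 2635256–2636191 and 2635358–2636078 in the first region and 2700464–2702023 and 2700557–2701586 in the second, and were joined to them only by merging. In library D the highest peak of each of these regions, 2634456–2637719 and 2697084–2704223, overlapped the glucose A peak. In the second region lower peaks of A, B and C without glucose overlapped it as well, at 2698280–2698591, 2697400–2698999 and 2698291–2698599. For a single region called in 4 of 4 and 0 of 2 libraries, Fisher's exact test cannot go below 0.0667.

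**Figure D2:**
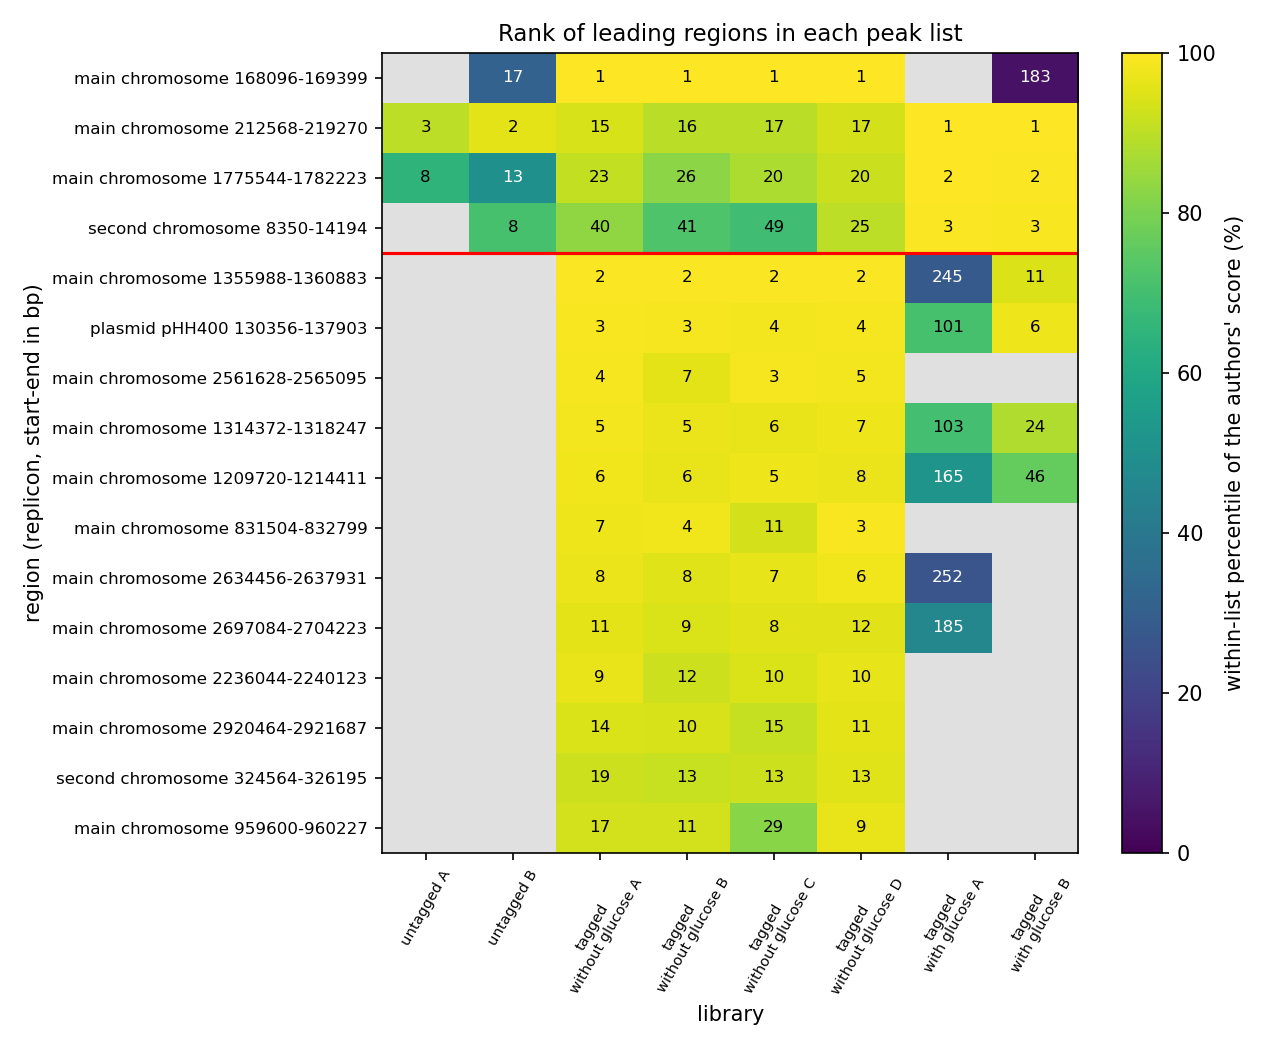
Within-list percentile of the authors' score (colour, in %) for 16 regions in the 8 peak lists, with the rank printed in each cell and grey where a list has no peak. Above the red line are 4 leading regions that overlap an untagged peak; below it are the 12 regions with the highest mean percentile without glucose among the 121, of which 6 have no peak in either glucose list.

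With glucose, 123 regions had a peak in both tagged libraries and in no untagged library. Both untagged libraries came from medium without glucose, so background particular to medium with glucose was not measured. Of the 30 not reproducible without glucose, 19 had a peak in some libraries without glucose and 11 had none. All 11 lay on the main chromosome. Main chromosome 2088669–2089169 had the highest mean percentile of them over the glucose lists, 54.7 (71.3 in list A), followed by 2004–2504 (50.2), 2890269–2890602 (44.9) and 2836161–2836828 (41.8). Main chromosome 612222–612722 had a mean percentile of 40.4. The lowest of the 10 named by the rule, main chromosome 229625–229998, had 19.6. The 123 regions require both libraries, and they numbered 79 in the upper 50% of each list, while glucose library A alone gave 322 untagged-free regions. Regions with a peak in exactly 1 tagged list and no untagged peak numbered 180, of which 115 were found in glucose library A alone.

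The difference between media in the amount called lay within the spread between libraries. Tagged cells with glucose gave 266.5 ± 107 peaks (SD, n = 2) over 199 ± 143 kb, and the values without glucose were lower, by a difference of −71.8 peaks (exact permutation p = 0.4, two-sided) and of −63.8 kb (exact permutation p = 0.533, two-sided). When tagged glucose library A was left out, the differences turned to 3.75 peaks and 37.0 kb, with the higher value in the medium lacking glucose.

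**Figure D3:**
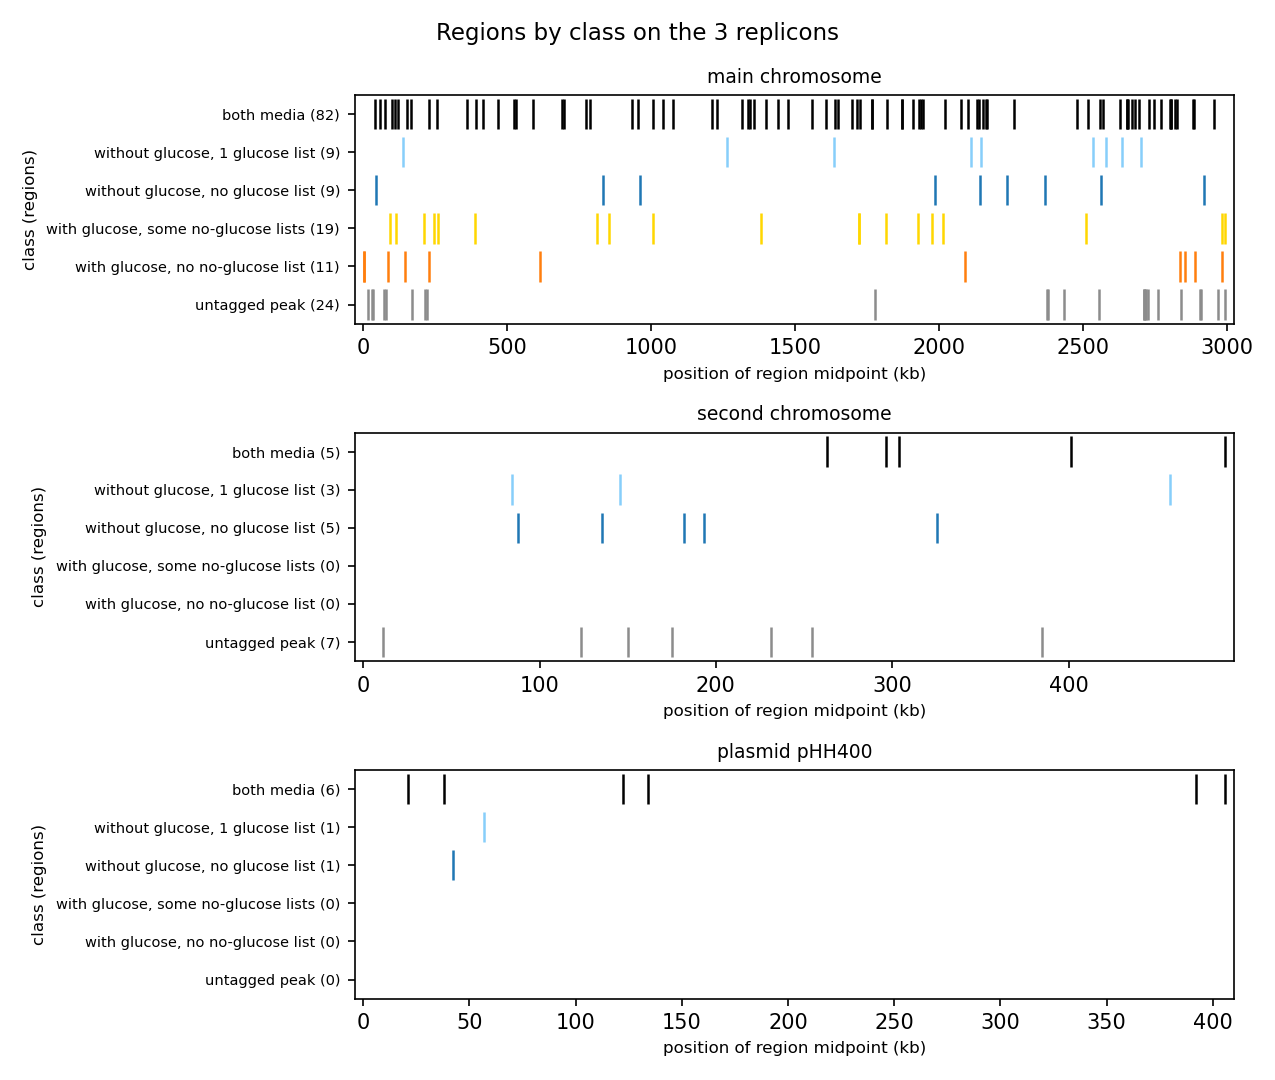
Midpoints of the regions (vertical ticks; x axis in kb, with the last called base taken as the replicon's length) on the 3 replicons, in rows by class with the number of regions in brackets. Regions reproducible in both media are spread along the main chromosome (82 of 93), the 15 in no glucose list lie on all 3 replicons, and the 11 called only with glucose lie on the main chromosome.

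Lists without glucose were on average more alike than lists from different media, and for the pair of glucose lists the measures disagreed. The mean Jaccard index over bases was 0.452 for the 6 pairs without glucose, 0.282 for the glucose pair and 0.344 for the 8 pairs across media. The index cannot exceed the ratio of the covered lengths of a pair. Glucose A covered 300 kb and glucose B 98.7 kb, so unequal length holds the index of the glucose pair down. The length of glucose A also limits its pairs across media. All pairs within a medium averaged 0.428, a difference of 0.0841 from the pairs across media (exact permutation of the medium over 15 splits, one-sided p = 0.133). The difference was 0.0499, 0.0421 and 0.0452 when no-glucose A, no-glucose B and glucose A were left out in turn, and 0.172 when glucose B was left out. Measured by the share of peaks with a partner the difference was 0.0865, with p = 0.0667 in the same exact test, the smallest value it can give. All 28 pairs of lists shared more peaks than circular shifts gave. Across the 6 pairs without glucose 85.0% of the shorter list's peaks had a partner (7.98% after shifts), across the 8 pairs from different media 75.7% (10.4%), and for the glucose pair 83.2% (13.4%). The highest adjusted permutation p among the 28 was 0.0002, and the smallest raw p that the 10000 shifts can give is 0.0001.

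The number of reproducible regions per replicon was set against replicon length. Without glucose, the main chromosome held 100 (93.2 expected from length), the second chromosome 13 (15.2 expected) and pHH400 8 (12.6 expected), and none departed from its expected number (lowest adjusted permutation p = 0.311 by random placement). When a peak in 2 libraries sufficed, pHH400 held 9 regions against 17.5 expected (adjusted permutation p = 0.0402 by random placement) and the main chromosome 144 against 129 (adjusted p = 0.0288). The glucose regions were tested after the data had been examined, and the second chromosome held 5 against 15.5 expected (adjusted permutation p = 0.0036 by random placement), pHH400 6 against 12.8 (adjusted p = 0.047) and the main chromosome 112 against 94.7 (adjusted p = 0.0018). Regions in exactly 1 tagged list were also fewer on pHH400, with 5 against 18.8 expected, and more on the main chromosome, with 159 against 139 (adjusted permutation p = 0.0009 for both).

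Peaks in reproducible regions scored higher than the other peaks of their list in 5 of the 6 tagged libraries. The median within-list percentile was 64.6 against 31.2 in library A without glucose, 56.9 against 20.7 in B and 66.4 against 29.7 in D. With glucose it was 78.8 against 33.2 in A and 57.9 against 33.0 in B. In library C without glucose it was 52.6 against 43.3, which did not pass (permutation test, adjusted p = 0.367). With peaks in regions that have an untagged peak left out, only 6 other peaks remained in C, and the medians of 52.6 and 19.7 differed (adjusted permutation p = 0.0391). In the 5 other libraries the adjusted p was at most 0.000456 with all peaks.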

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

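The tests of explanations in this part were chosen only after the results they concern had been seen. Of 60 groups of 4 libraries without glucose that were checked for a single library far from the others, 6 were flagged, and chance flags about 1 in 20. All 6 are within-list percentiles of a named region, and 5 of them concern library B. Second chromosome 149940–150599 stood at percentile 66.2 in B, below the other libraries. Plasmid pHH400 20708–21215 stood at 21.4 in B, also below the others. Main chromosome 2561628–2565095 stood at 95.9 in B, main chromosome 2804264–2804999 at 60.7 and main chromosome 2821465–2822135 at 51.0, all below the other libraries. Plasmid pHH400 405309–405959 stood at 91.6 in library A, above the others. Library B has the shortest of the 4 lists, with 145 peaks, and a given rank stands at a lower percentile in a shorter list. Main chromosome 2821465–2822135 ranked 72 in B, against 65 in A and 70 in D, whose lists are longer. In C, with 156 peaks, it ranked 40.

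Among the 12 regions with the highest mean percentile without glucose, 6 had no peak in either glucose list, against 1.49 expected if the 15 such regions were spread evenly over the 121 (exact hypergeometric test, one-sided p = 0.000788). A lower sensitivity of the glucose libraries that keeps the order of the regions should lose the strongest least. Every one of the 121 regions missing from list A was also missing from list B, so a test of list A alone repeats the one above. List B lacked 8 of the 12, those 6 among them (2.78 expected, p = 0.000857 in the same exact test). All 12 leading regions of the glucose lists were called in each of the 4 lists without glucose. The bins of the peak caller are argued against by lists left out of the choice of regions: of the 10 leading regions picked in no-glucose B and D (bins of 200 and 204 bp), A and C at 104 and 103 bp each called 10 and glucose A and B at 167 and 103 bp called 6 and 4, and of the 11 picked in A and C, B and D called 11 and the glucose lists 7 and 5, so at least 4 fewer with glucose. For the other 109 reproducible regions sensitivity stays open: the 9 without a glucose peak had a median percentile 17.5 below that of the regions in both glucose lists (difference of −17.5, permutation p = 0.0809). At the strong regions, the medium itself and a lower yield of TrmB-bound DNA over an unchanged background in these glucose libraries may each account for the loss, and neither was tested.

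Regions called in all 6 tagged libraries overlap the untagged background. Of 44 untagged peaks, 24 lay in such regions, against 2.50 after circular shifts (permutation p = 0.0001, the smallest the shifts can give), as a background shared with untagged cells would give for the 12 of 81 regions concerned. The 69 without an untagged peak had a median percentile 11.7 lower in the tagged lists (difference of −11.7, 74.3 against 86.0, permutation p = 0.0201), so weaker background sites under the untagged lists' threshold could be among them. A lower percentile would also be seen for weak sites of TrmB, and these data leave both open for the 69 as a set. Not all of them are weak, since 4 of the 69 hold the first 4 ranks among the 81 in every list without glucose.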

How the results depend on the processing

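Of 106 alternative values for the results that answer a comparison, 95 kept their direction and side of the threshold or stayed within 1.5 times the main count. The exact permutation tests of peak number, covered length and similarity cannot reach 0.05 in any setting. For those values only the direction could change. The greater peak number and covered length of tagged over untagged libraries held in every setting run, with differences of 157 to 189 peaks and 94.8 to 142 kb when each library was left out. Between media the differences ranged from −147 to 3.75 peaks and from −165 to 37.0 kb when each library was left out, and they turned to 3.75 peaks and 37.0 kb with tagged glucose library A left out, which has the longest list. With only the upper 50% of each list by score, 67 regions were reproducible without glucose, 79 with glucose and 49 in both. Fewer peaks enter then, but the untagged lists are cut as well, so fewer regions could be set aside. The 67 thus need not all be among the 121. Requiring 2 libraries raised the regions reproducible without glucose and in no glucose list from 15 to 26, as the rule is looser. This count ranged from 15 to 28 when each library was left out, with 26 when no-glucose library C and 28 when glucose library A was missing. Regions without glucose ranged from 121 to 167, regions in both media from 93 to 107, and regions with glucose from 123 to 322, the highest with glucose library B left out, since a single list then sets the count. Leaving out a tagged library loosens the rule, and leaving out an untagged one sets fewer regions aside. These counts and the count of 15 could thus hardly fall, and their ranges do not measure stability. With 2 libraries required, the ratio of observed to expected regions passed the threshold on pHH400 (0.513) and the main chromosome (1.11), with more regions tested; the second chromosome did not pass under either rule. The similarity difference ranged from 0.0421 to 0.172 when each library was left out. All 28 list pairs also passed with midpoints within 250 bp, and all 6 lists passed the score comparison once peaks in regions with an untagged peak were left out, a setting chosen after seeing the data. For 69 named regions under 13 settings, the share of lists without glucose minus the share with glucose was equal in 828 of 897 cases, moved in 69 and changed sign in 0. A region called in all 6 tagged lists has a difference of 0, which was never counted as a change of sign. One named for peaks in a single medium could hardly change sign either, so that count follows largely from the naming rule. Read totals are unknown, so a missing peak at any single region was not separated from a shallow library. For the 12 leading regions without glucose as a set, the values argue only against a loss that keeps the order of the regions.

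Letters A and B occur in both media, but nothing in the labels ties a letter to a culture, and lists with the same letter were no more alike across media (mean Jaccard index 0.324) than lists with different letters (0.340). With the replicate block, the difference between media was −75.5 peaks and −75.8 kb, 71 regions were called in both media, and the similarity difference was 0.0283; none of these changed its direction. The planned results on positions outside genes, start-codon windows, 17 gene lists and the TrmB motif were not run, since they need a genome that was not used here.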

Other observations

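The comparison of replicons was chosen only after the values were seen, and the test of rank order before its result was seen. Regions reproducible without glucose lacked a glucose peak more often on the second chromosome than elsewhere. There 5 of 13 had no peak in either glucose list (38.5%), against 9 of 100 on the main chromosome (9%) and 1 of 8 on pHH400 (12.5%), with Fisher's exact p = 0.0106 for the second chromosome against the others, two-sided and not adjusted. Leaving out each library in turn gave p between 0.00148 and 0.0278. With glucose A left out the counts were 8 of 13 on the second chromosome and 20 of 112 elsewhere, and with no-glucose A left out they were 6 of 14 and 16 of 115. The 5 regions were 324564–326195, in all 4 lists without glucose, and 87720–88331, 135252–135799, 181600–182311 and 193188–193599, each in 3 of them and none above percentile 47.5 on average. All 4 of the latter lacked a peak in no-glucose library C as well, which has 12 peaks on the second chromosome, against 21, 28 and 19 in A, B and D and 18 and 9 in glucose A and B.

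Ranking the 81 regions called in all 6 tagged lists against each other removes the difference in list length. The hypothesis was that this order follows the medium. Spearman's rho over these regions averaged 0.750 for pairs of lists within a medium and 0.580 across media, a difference of 0.170 against 0.102 for the highest of the 14 other splits. Regions are not independent replicates, and 15 splits are too few for a share under 0.05. With the mean score of a region's peaks in place of the highest, the difference was 0.141. The pair of glucose lists had a rho of 0.569, and pairs without glucose had 0.708 to 0.875. The difference rests on 4 regions that hold the first 4 ranks in every list without glucose. When these were left out, a test added after the values were seen, the difference over the other 77 regions was 0.0544 and another split reached 0.0558.

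These 4 regions ranked far apart in the 2 glucose lists. Among the 81, main chromosome 1355988–1360883 ranked 81 in glucose A and 11 in glucose B, plasmid pHH400 130356–137903 ranked 69 and 6, main chromosome 1314372–1318247 ranked 70 and 24, and main chromosome 1209720–1214411 ranked 78 and 44. Ranks within a fixed set displace each other, so the remaining 77 were also ranked without them. There 6 regions stood higher in every list without glucose than in either list with glucose and 13 the other way, against 10.3 expected in all if libraries were exchangeable. Of the 13, 3 overlap an untagged peak (main chromosome 212568–219270 and 1775544–1782223 and second chromosome 8350–14194), and of the 6, 2 do (second chromosome 384678–385355 and main chromosome 2759100–2760509). The latter stood higher with glucose among the 81, at mean ranks of 5.75 without and 4 with glucose, and turned only because the 4 leading regions above it were removed. Of the 6, only main chromosome 2657304–2659307 was also higher in every list without glucose among the 81. The counts there were 5, with the 4 leading regions among them, and 15 the other way. The mean rank of main chromosome 1909478–1910145 was 58.1 without and 29 with glucose, and that of main chromosome 2657304–2659307 was 10.5 and 35.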
